A study of Mus musculus with 8 samples.

How the data were processed

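H3K36me3 ChIP-seq was done on bone marrow stromal cells of floxed Setd2 mice of the C57BL/6J strain at passage 2, per the labels' protocols. The cells were infected with a lentivirus for GFP (WT) or Cre (KO), selected in puromycin at 2 µg/ml for 4 days and fixed with formaldehyde at 1% for 10 min. The series holds 4 H3K36me3 libraries, 2 per genotype, and 4 control libraries, an Input and an IgG library per genotype. Groups and replicate numbers were taken from the sample titles.

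Reads were aligned with Bowtie2 to GRCm38, per the submitters' processing notes, which give no version. The authors deposited 8 peak lists, 2 per H3K36me3 library, each called on a single library against the Input or the IgG library of the same genotype, per the labels. The peak names start with MACS, and the version and settings of the peak caller are not given in the sources used here. The deposited score of each peak is the authors' own value, with 13.01 as its smallest. That number equals -10 times log10 of a p-value of 0.05, the form in which the MACS 1 peak caller writes scores, but the scale is not stated. The score was used only to describe and filter peaks within a list. Both libraries of a genotype were called against the same Input and IgG libraries, so a flaw of a control library is shared by both replicates. The lists hold no read counts, so the depth per library is unknown, and a deeper library would give more and wider peaks. The level at which a region stops being called therefore cannot be put on a scale of reads, and a gene without a peak has no upper limit for its signal. A table of merged peaks with annotation, named in the labels, was not used here.

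Peaks on chromosomes 1 to 19, X and Y were read as BED intervals and used as listed, except where merging is named. Positions are printed counted from 1. Gene spans came from the RefSeq gene table of GRCm38.p6, the build of the peak lists, with 21887 protein-coding genes among 49943 annotated genes on these chromosomes (2704 Mb). The table used gives neither strand nor exons. Per gene, coverage was the percent of its span under peaks. The 20 equal bins along genes were therefore folded from either edge to the middle, and covered bases were split into protein-coding spans, other annotated genes and the rest. These substitutes were chosen after the tables had been seen. A region counted as shared if at least 1 bp was common. Overlap by chance was measured by moving the peaks of a KO library around each chromosome 100 times.

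Whole-list measures were compared by exact two-sided permutation tests of the 4 libraries, whose smallest p is 0.333. Coverage of genes was tested KO against WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust options, statmod 1.5.0) on the percent scale, in genes with a mean over the 4 libraries of at least 10%, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. This mean filter keeps genes that fell, and it lets in short genes covered by a single peak. Of 21 gene lists, 15 were written out and 6 were taken by name patterns. They covered the osteoblast, adipocyte and chondrocyte lineages, stromal, haematopoietic and endothelial markers, neuronal genes, H3K36 writers, erasers and readers, RNA polymerase II elongation, splicing factors, DNA repair, cell cycle, collagens and matrix, TGF-beta, BMP and Wnt signalling, lipopolysaccharide response, ribosomal proteins, the respiratory chain, olfactory and vomeronasal receptors, histones, zinc finger genes and the proteasome. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Overlaps and summaries were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9.

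The samples, tests, gene lists and most alternatives were fixed before the data were examined. So was the rule for the genes named: Setd2, Lbp, Runx2, Sp7, Alpl, Col1a1, Bglap, Pparg, Cebpa, Fabp4 and Lpl; the 10 largest falls and up to 10 largest rises past the threshold among genes of at least 10 kb with both KO libraries on one side of both WT libraries; the 5 genes of at least 20 kb with the highest KO coverage; and per list up to 2 tested members with the largest fall and up to 2 with the smallest fall or a rise. Of the 10 largest falls, 1 gene is not reported here. Other genes in the text were chosen after their values were seen.

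The limma step was tested on simulated coverage of 11644 genes. The spread was that of the WT pair at the same WT coverage, given to the simulated KO libraries as well. The spread of the KO pair was not used. With 200 genes changed, 64 of the 100 changed by 30 points and 27 of the 100 changed by 20 points were called, as were 3 of 11444 unchanged genes. With coverage lost in all but 200 genes, 84.3% of the lost genes were called, but so were 23 of the 200 left unchanged (11.5%). Of these 23, 8 were called higher and 15 lower. Calls among covered genes that keep coverage were thus too frequent in this simulation, and may be so in the data. Genes without a WT peak were not simulated. The interval arithmetic was checked against a base-by-base count in 200 simulated sets, with 0 mismatches.

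Alternatives covered the IgG lists, bases covered against both controls, peaks at or above the pooled median score of 37.6, merging of peaks within 1 kb, an equal number of top peaks, overlap of 10% and 50% of a region, leaving out each library, the replicate number as a block, an arcsine scale, scaling to each library's mean coverage, filters of 25% and none, eBayes without trend, genes of at least 20 kb for position and an estimated correlation. Added after the data had been seen were genes of at least 5 kb only and the application of these settings to the chromosomes, the length groups and the count of named genes that fell. Coverage of exons only and of the downstream part of genes was planned and not run, since the gene table used gives no exons or strand.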

Results

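Trimethylation of histone H3 at the lysine written by Setd2 (H3K36me3) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse bone marrow stromal cells. These adherent marrow cells include progenitors of bone, fat and cartilage. The cells came from C57BL/6J mice with a floxed Setd2 gene and received either a GFP lentivirus, which leaves the gene intact (WT), or a Cre lentivirus, which deletes the floxed part (KO). Each genotype had 2 H3K36me3 libraries, 1 Input library of chromatin without antibody and 1 IgG library of a non-specific antibody. The labels do not say that the 2 libraries of a genotype came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The measurements were lists of H3K36me3 peaks, called by the authors for each library against the Input of the same genotype and, separately, against its IgG. The lists against Input are the values given here unless IgG is named. The 4 lists held 242745 and 246258 peaks in WT and 122589 and 159459 peaks in KO, and the read depth behind them is unknown. Means are given ± SD over the 2 libraries of a genotype (n = 2), and the coverage of a gene is the percent of its annotated span that lies under peaks.

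The first question was how the H3K36me3 peaks over Setd2 itself differed between the genotypes. Setd2, the methyltransferase that places this mark on the bodies of transcribed genes, lies on chromosome 9 from 110532500 to 110618633 (GRCm38). In WT, 66.4% and 60.5% of its span was covered, by 52 and 45 peaks. In KO, 0.690% and 1.70% was covered, by 1 and 3 peaks. Coverage of Setd2 therefore fell from 63.4% ± 4.19 to 1.20% ± 0.716, with a limma adjusted p of 0.000259. Peaks of the mark over a gene do not measure whether its exons are present, so these values are no check of the deletion. Of the neighbouring genes, Nradd, the nearest, had 65.4% and 59.6% in WT and 0% and 15.1% in KO, Kif9 had 18.0% and 26.5% in WT and 9.03% and 10.7% in KO, and Nbeal2 had 44.8% and 54.7% in WT and 10.7% and 5.16% in KO.

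**Figure D1:**
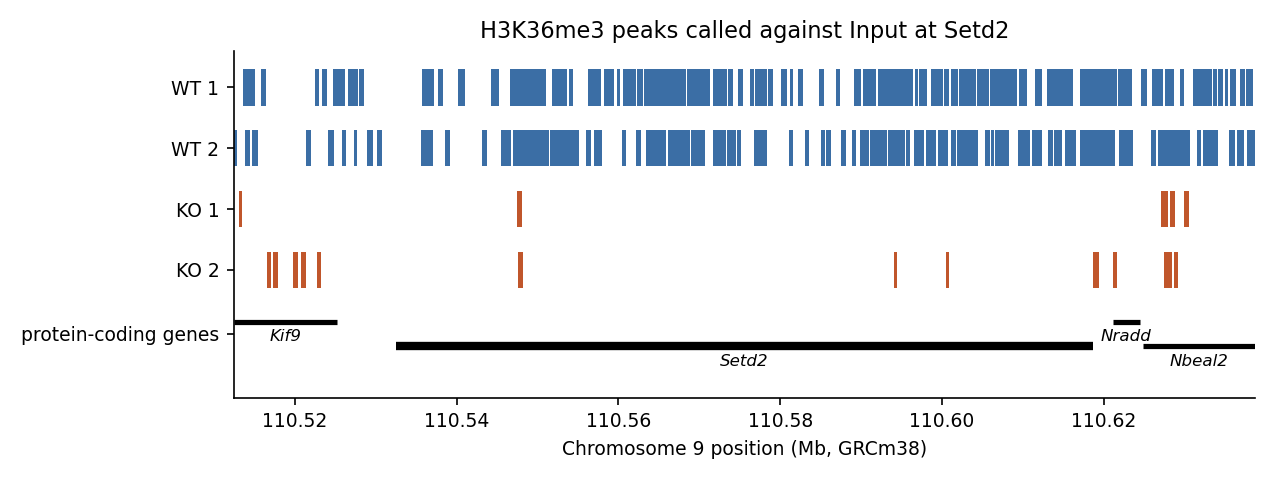
Map of the H3K36me3 peaks called against Input at Setd2 and 20 kb to either side, by position in Mb on chromosome 9 (GRCm38). Each blue (WT) or red (KO) block is 1 peak in 1 library, and black bars are protein-coding gene spans. The 52 and 45 WT peaks fill most of Setd2, against 1 and 3 peaks in KO.

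The main comparison asked how much of the genome carried H3K36me3 peaks without Setd2. Peaks covered 239.0 Mb ± 5.11 of the genome in WT and 83.0 Mb ± 16.0 in KO, a ratio of KO to WT of 0.347. The number of peaks was 244502 ± 2484 in WT and 141024 ± 26071 in KO, a ratio of 0.577. The broad domains typical of the mark over gene bodies were nearly gone from the KO lists. Mean peak width was 978 bp ± 30.8 in WT and 588 bp ± 4.95 in KO, and 8.09% of WT peaks but 0.0716% of KO peaks were wider than 2 kb. The widest peak spanned 39801 bp in WT and 7535 bp in KO. Each of these differences was larger than the spread between libraries, and both KO libraries lay on 1 side of both WT libraries. The exact two-sided permutation p was 0.333 for each, which is the smallest that 2 libraries against 2 can give. The authors' score of a peak was at least 100 in 15.3% of WT peaks and 1.61% of KO peaks, which describes each list and depends on its read depth. The direction for the number of peaks depends on how fragments are counted: once peaks within 1 kb of each other were merged, KO had 1.11 times as many as WT.

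**Figure D2:**
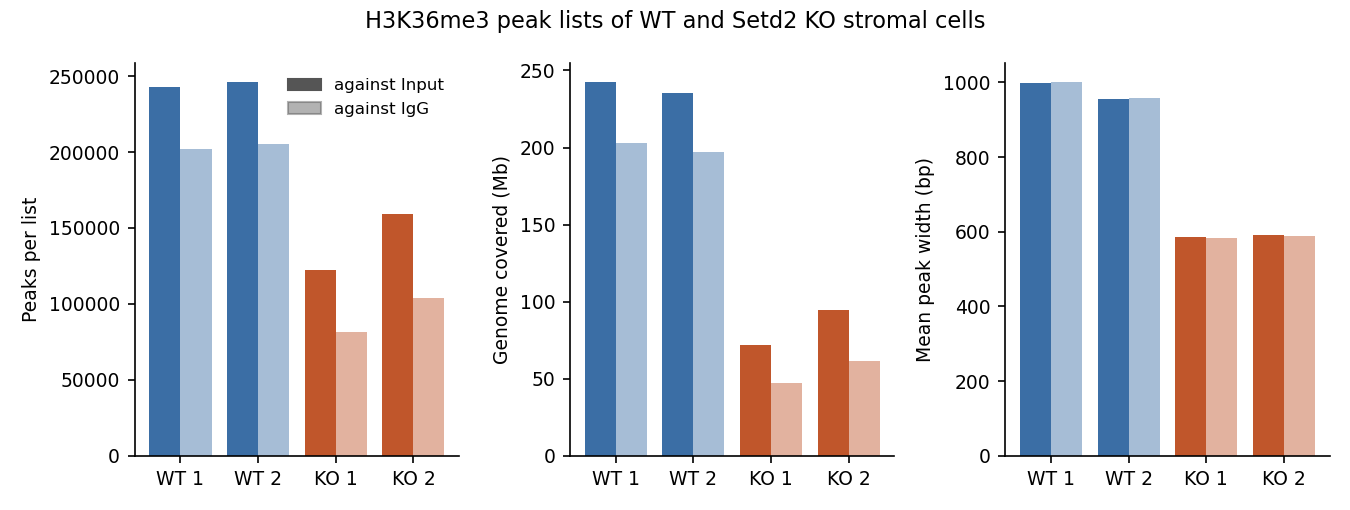
Number of peaks, genome covered (Mb) and mean peak width (bp) in each of the 4 H3K36me3 libraries, with 1 bar per library and control; dark bars are lists called against Input and pale bars against IgG. Every WT bar stands above every KO bar, with 242.6 and 235.4 Mb covered in WT and 71.7 and 94.4 Mb in KO against Input.

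Shared positions were then compared. The WT libraries had 44.0% of their covered bases in common (shared over union), whereas WT and KO libraries had between 4.07% and 4.78% in common. The KO libraries had 5.22% in common, and 11.5% and 8.73% of the covered bases of each KO library were covered in the other. Of the 212612 regions covered in both WT libraries (146 Mb), 82.2% held no base of a peak from either KO library. Of the 22927 regions covered in both KO libraries (8.24 Mb), 59.4% held no base of a WT peak. The share of KO bases that fell on regions covered in both WT libraries was 10.8% and 10.1%. After moving the KO peaks along the chromosomes 100 times, it was 5.71% and 5.69% on average, so the observed overlap was 1.90 and 1.78 times that of the moved peaks. No shift reached the observed value, the highest giving 5.99% and 5.91%. These shares of regions depend on how many KO peaks are counted, and merging peaks within 1 kb lowered the WT regions without a KO peak to 65.6%.

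In WT the mark lay in genes, and in KO the peaks lay much as the genome does. Protein-coding gene spans held 85.3% ± 0.277 of the covered bases in WT and 39.3% ± 0.170 in KO, beside 38.2% of the genome. Space outside annotated genes held 12.0% ± 0.214 in WT and 51.3% ± 0.133 in KO, beside 53.9% of the genome. These are shares of 239.0 Mb in WT and 83.0 Mb in KO. Covered bases outside annotated genes were thus more in KO than in WT, while those in protein-coding spans were fewer. Other annotated genes, such as long non-coding RNA genes and pseudogenes, held 2.67% ± 0.0635 and 9.41% ± 0.0373. The exact permutation p was 0.333 for each class, the smallest possible here. Fewer bases were covered in KO on every autosome: the ratio of KO to WT ran from 0.231 on chromosome 11, the most covered in WT, to 0.437 on chromosome 13, with a median of 0.338 over the 19 autosomes. The X chromosome stood apart, with 2.33% covered in WT and 2.19% in KO, a ratio of 0.940. This ratio turned above 1 without KO replicate 1 (1.08) and with only peaks at or above the median score (1.32). On the Y chromosome coverage was 0.103% in WT and 0.115% in KO.

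The comparison of single genes asked which genes lost or kept the mark. Of the 21887 protein-coding genes, 4880 were covered over at least 50% of their span in both WT libraries and 12 in both KO libraries. Among those 4880 genes, 4348 (89.1%) were covered under 10% in both KO libraries and 23 were covered at 25% or more in both. Mean coverage of a gene was 26.3% and 25.5% in WT and 2.92% and 3.72% in KO. The limma test covered the 10809 genes with a mean coverage of at least 10% over the 4 libraries. Coverage fell in 10013 genes (92.6%), rose in 60 and did not pass the threshold in 736. The median change was -47.7 percentage points. The share that fell depends on the filter: without it, 10701 of 18288 genes fell (58.5%). With the same threshold on p before adjustment, 10031 of the 10809 genes fell and 60 rose. Because most tested genes fell, the adjustment hardly changed the calls. It left the 60 rises little protection against false calls from many tests. Scaling each library to its own mean coverage would remove a loss of equal proportion in all genes. After it, the median change was -16.7 points, 4890 genes were lower and 261 higher. Lower genes then made up 94.9% of the calls, beside 99.4% without scaling.

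Large falls among genes of at least 10 kb emptied whole gene bodies. Setd1a, a histone methyltransferase of another residue, fell from 90.4% ± 1.23 to 0% in both KO libraries. Rnf213, a ubiquitin ligase, fell from 90.4% ± 0.551 to 1.46% ± 0.527. Anapc2, a subunit of the anaphase-promoting complex, fell from 92.8% ± 0.179 to 4.46% ± 6.30, and Gpi1, an enzyme of glycolysis, from 91.1% ± 1.19 to 2.40% ± 3.39. Coverage of 2610507B11Rik, Safb2, Hmgxb3, Ttll3 and Dnttip2 fell by 88.2 to 89.8 points, although against IgG Hmgxb3 had only 50.4% in WT and 1.26% in KO. The limma adjusted p was 0.000211 for each of these genes except Anapc2, at 0.000233. After scaling, Gpi1 and Anapc2 no longer passed.

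**Figure D3:**
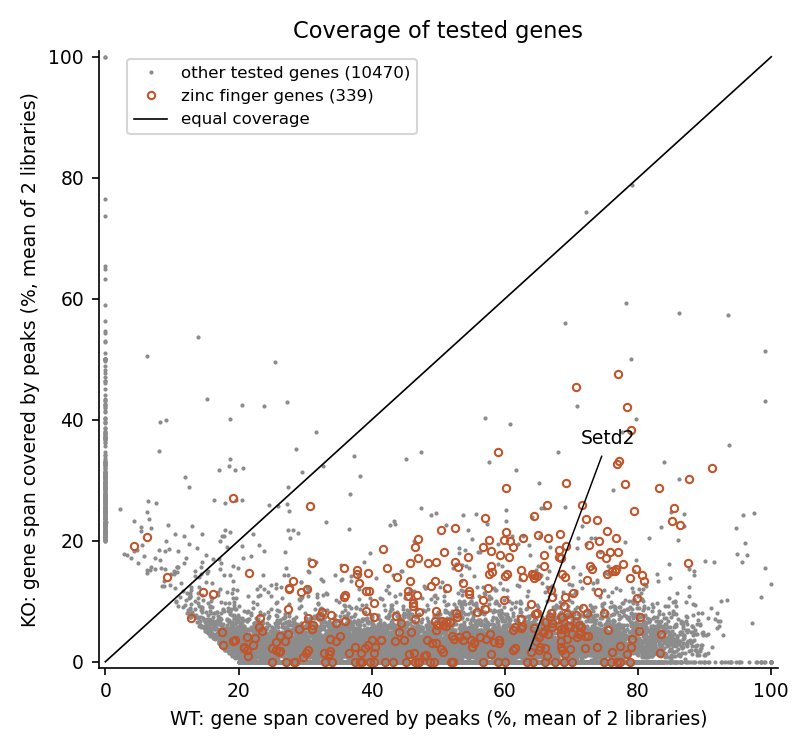
Percent of the gene span covered by peaks in WT (horizontal axis) and KO (vertical axis), each the mean of 2 libraries, with 1 point per tested gene. Nearly all points lie below the line of equal coverage, Setd2 among them (63.4% in WT and 1.20% in KO). Open red circles are the 339 tested zinc finger genes, whose median change was -45.8 points and, once libraries were scaled to their mean coverage, 2.10 points.

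The 60 genes with higher coverage in KO were mostly short. Their median length was 2.44 kb, beside 22.8 kb for the lower genes, 42 of the 60 had no WT peak in either library, and 13 were olfactory or vomeronasal receptor genes. Only 9 were at least 10 kb long. Gm2808 rose from 18.8% ± 1.97 to 40.1% ± 3.04 (limma adjusted p 0.00288), but had 11.2% in WT and 12.7% in KO against IgG, and the adjacent Gm29721 rose from 6.93% ± 1.25 to 22.1% ± 7.26. The zinc finger genes Zfp981, Zfp660 and Zfp978 rose by 14.8, 14.3 and 7.96 points. Gml2, Ms4a10, Cks1brt and Ces2h rose by 11.4, 10.8, 10.7 and 9.72 points, but Ces2h was lower in KO against IgG, with 7.15% in WT and 4.40% in KO. Without WT replicate 1 or without WT replicate 2, none of these 9 genes passed, without KO replicate 1 or 2 there were 4 and 1 left, and against IgG only 1 of the 7 tested passed while Zfp660 and Zfp978 turned lower. The count of 60 itself became 27 and 26 without WT replicate 1 and 2, 200 and 155 without KO replicate 1 and 2, and 21 against IgG. In simulated libraries with coverage lost in most genes, 23 of 200 genes left unchanged were called (11.5%), 8 as higher and 15 as lower. Calls among covered genes that keep coverage were therefore too frequent there, and may be so in the data. The simulated KO libraries had the spread of the WT pair, not that of the KO pair. All simulated genes had at least 10% WT coverage, so this rate does not cover the 42 rises without a WT peak.

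Among genes of at least 20 kb, KO coverage was highest in Zfp992 and Zfp991, 2 zinc finger genes on chromosome 4. Zfp992 fell from 70.7% ± 10.8 to 45.5% ± 3.17 (limma adjusted p 0.0239) and Zfp991 from 78.3% ± 0.5002 to 42.1% ± 6.28 (limma adjusted p 0.00237). Gm51425 fell from 57.0% ± 5.65 to 40.4% ± 7.95, with a limma adjusted p of 0.0488. After scaling to mean coverage all 3 of these were higher in KO, and each lost its call without WT replicate 1 and without WT replicate 2. Zfp992 also lost it without either KO library and against IgG, where it had 51.8% in WT and 30.4% in KO. Gm2808 was also among these 5 genes. Mroh2a had 65.7% in KO replicate 1 and 14.2% in KO replicate 2 beside 9.16% ± 0.160 in WT, a difference within the spread of KO (limma adjusted p 0.204).

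The lists of genes fixed before the data were examined showed what the stromal cells lost. Of 28 stromal cell markers, 18 passed the coverage filter and all 18 fell (11 after scaling). Vim, the intermediate filament of mesenchymal cells, fell from 87.2% ± 7.07 to 7.55% ± 10.7, and Col6a1, a collagen chain, from 68.9% ± 10.6 to 0%. The transcription factor Prrx1 fell from 25.5% ± 4.57 to 0%, and Col3a1 from 29.4% ± 8.46 to 0.909% ± 1.29. Of 43 collagen and matrix genes, 38 were tested and 37 fell (17 after scaling). P4hb, which hydroxylates collagen chains, fell from 83.9% ± 1.16 to 2.22% ± 3.13, Thbs2 by 73.6 points and Col8a1 by 19.5 points. The exception was Timp1, an inhibitor of matrix proteases, with 20.8% ± 8.61 in WT and 3.93% ± 5.55 in KO (limma adjusted p 0.0531). The signal over several of these genes depended on the control: against IgG the WT libraries had no coverage of Vim, Col1a1 or Timp1, and 12.1% of Thbs2. Sparc and Bmp1, named below, had 21.7% and 29.1% in WT against IgG, and Lyz2 had 0%.

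In the osteoblast lineage list, 14 of 30 genes were tested and 13 fell, but only 6 fell against IgG and 7 after scaling. Col1a1, the main collagen of bone, fell from 68.8% ± 6.32 to 1.72% ± 2.44, and Sparc, a bone matrix protein, from 68.2% ± 2.48 to 3.24% ± 1.40. Runx2, the master transcription factor of osteoblasts, fell from 17.6% ± 0.0386 to 3.73% ± 0.943 (limma adjusted p 0.00471). Bglap2, an osteocalcin gene of under 1 kb, had 0% in WT and 0% and 57.8% in KO and did not pass. Sp7, Alpl and Bglap were below the filter: Sp7 had 1.505% ± 2.13 in WT and 0% in KO, Alpl had 1.39% ± 0.545 and 2.88% ± 2.31, and Bglap had 0% and 9.67% ± 13.7. In the adipocyte lineage list, 15 of 30 genes were tested and 13 fell (5 after scaling). Fasn, the fatty acid synthase, fell from 82.8% ± 3.36 to 5.12% ± 3.29, a call that was lost against IgG, where WT coverage was 43.4%. Stat5a fell by 74.1 points, Adipor2, a receptor of adiponectin, by 20.3 points and Lpl, the lipoprotein lipase, from 28.3% ± 1.18 to 7.15% ± 2.75. Fabp4, a fatty acid carrier, had 27.4% ± 18.6 in WT and 6.44% ± 9.11 in KO (limma adjusted p 0.149), and Klf15 had 14.7% ± 2.09 and 7.30% ± 4.93 (limma adjusted p 0.115). The regulators of fat cell formation Pparg and Cebpa were below the filter, with 9.03% ± 0.0988 and 0% in WT and 2.75% ± 0.801 and 0% in KO. In the chondrocyte list only 3 of 20 genes were tested, Col11a2, Col9a3 and Col10a1, and they fell by 43.0, 40.1 and 38.0 points.

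Markers of other cells in the marrow were compared in the same way. Of 32 haematopoietic markers, 17 were tested and 16 fell. This count became 8 without WT replicate 1, 8 without WT replicate 2 and 3 after scaling. Lyz2, the lysozyme of myeloid cells, fell from 81.3% ± 8.996 to 5.72% ± 8.08, and Cd68, a macrophage glycoprotein, from 54.2% ± 24.2 to 0%. Lcp1, an actin-bundling protein of leukocytes, fell from 18.2% ± 3.23 to 4.15% ± 0.831. Cd79b, a part of the B cell receptor, had 19.1% ± 27.0 in WT and 15.9% ± 22.5 in KO (limma adjusted p 0.875). Mean coverage over all 32 markers was 20.7% ± 2.15 in WT, close to the 21.1% ± 1.29 of the osteoblast list. Only 1 of 20 endothelial markers was tested, Egfl7, which fell from 20.3% ± 0.817 to 3.25% ± 0.963. This call was absent against IgG, with the higher scores, after scaling, at a filter of 25% and without either WT library. Only 1 of 28 neuronal genes was tested, Tubb3, a tubulin, which fell from 38.6% ± 1.14 to 4.37% ± 1.20. Mean coverage over all neuronal genes was 2.92% ± 0.165 in WT and 2.32% ± 0.713 in KO.

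The machinery of transcription was among the most covered in WT. All 40 splicing factor genes and all 34 genes of RNA polymerase II elongation were tested, and all fell. Mean coverage of the splicing factors was 68.9% ± 2.22 in WT and 1.47% ± 0.0912 in KO. Prpf31 and Sf3a1 fell by 87.1 and 86.8 points and Srsf10 and Srsf2 by 33.6 and 37.9 points. The elongation genes had 63.8% ± 2.04 in WT and 2.10% ± 1.43 in KO. Supt6, a histone chaperone that travels with the polymerase, and Ctr9, a subunit of the Paf complex, fell by 82.5 and 81.4 points, and the kinase gene Cdk13 and the cyclin gene Ccnt2 by 25.3 and 31.1 points. Of the writers, erasers and readers of H3K36 methylation, 33 were found, 31 were tested and 30 fell. The reader Glyr1 fell from 89.3% ± 2.19 to 1.78% ± 1.04 and the reader Brd1 from 84.4% ± 1.69 to 0.728% ± 1.03. The DNA methyltransferase Dnmt3b and the demethylase Kdm2b fell by 21.9 and 27.5 points. All 27 tested genes of DNA mismatch and double-strand break repair fell, of 30 listed (9 after scaling), Msh6 and Mre11a by 67.9 and 66.0 points and Brca1 and Msh3 by 14.9 and 15.9 points. All 27 tested cell cycle genes fell, of 36 listed (11 after scaling), the cyclins Ccne1 and Ccnd1 by 78.9 and 72.2 points and the replication genes Orc1 and Cdc6 by 23.9 and 24.9 points.

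Of the signalling lists, 28 of 30 tested genes of TGF-beta, BMP and Wnt signalling fell, of 40 listed (16 after scaling). Dvl3, a transducer of Wnt signals, fell by 75.1 points, Bmp1 by 65.6 points and Sfrp1, a secreted Wnt inhibitor, by 16.1 points. Porcn, which acylates Wnt proteins, had 43.4% and 8.84% in WT and 4.46% ± 0.857 in KO (limma adjusted p 0.190). In the lipopolysaccharide response list, 26 of 27 tested genes fell, of 32 listed. The NF-kappaB subunit genes Rela and Relb fell from 83.5% ± 2.91 to 0% and from 79.2% ± 0.524 to 2.36% ± 0.134, and the adaptor Ticam2 by 23.6 points, a change that ran from -33.1 to -14.1 points when 1 library was left out. Il1b had 17.0% ± 1.15 in WT and 17.0% ± 1.54 in KO (limma adjusted p 0.998), but 4.42% and 0% against IgG. Lbp, the lipopolysaccharide binding protein, was below the filter with 12.5% ± 1.96 in WT and 1.81% ± 2.56 in KO, by 4 and 6 peaks in WT and 0 and 2 in KO.

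Housekeeping lists lost the mark over short genes as well. Of 84 ribosomal protein genes, 77 were tested and 68 fell, and the mean over all 84 was 52.1% ± 1.07 in WT and 0.242% ± 0.0150 in KO. Rps15a and Rps6 fell by 85.6 and 83.8 points. Rps27 and Rpl39l were covered in 1 WT library only, at 40.02% and 42.8%, and did not pass. Of 79 genes of the mitochondrial respiratory chain, 73 were tested and 71 fell (40 after scaling), Uqcrc1 and Atp5b by 85.8 and 82.0 points and Cox5a and Uqcrfs1 by 20.003 and 22.3 points. Of 39 proteasome genes, 38 were tested and 37 fell, Psmc4 and Psmd6 by 84.2 and 81.9 points and Psmd14 by 35.02 points. The exception was Psmb11, the thymus-specific subunit, with 11.5% and 47.1% in WT and 13.2% ± 0.316 in KO.

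The zinc finger, olfactory receptor and histone lists were compared next. Of 389 zinc finger genes, 339 were tested, 327 fell and 3 rose, with a median change of -45.8 points that became 2.10 points after scaling. After scaling 59 were lower and 18 higher, and without WT replicate 1 or 2 there were 202 and 213 lower genes. Their mean coverage was 48.0% ± 0.465 in WT and 8.89% ± 1.38 in KO, the highest KO mean of the 21 lists. Zfp276 and Zfp384 fell by 81.8 and 78.9 points. Of 1459 olfactory and vomeronasal receptor genes, a silent control, 210 were tested, 5 fell and 13 rose. The number that fell became 20 and 17 without WT replicate 1 and 2. Of the 210, 160 had no WT peak and passed the filter through KO peaks alone, so the direction of most of this tested set was fixed by the filter. The mean over all 1459 was 1.27% ± 0.0986 in WT and 4.54% ± 1.05 in KO. Olfr1377 and Olfr1339 rose from 0% to 76.5% ± 13.6 and 65.5% ± 0.970, and Olfr99 and Olfr1417 fell by 76.5 and 71.4 points. These genes are about 1 kb long, so 1 peak covers most of such a gene. Of 57 replication-dependent histone genes, 12 were tested, 3 fell and 2 rose, with a median change of -27.1 points that became 48.6 points after scaling. H3c4 fell from 100% to 0% in both libraries, H2ac1 rose from 0% to 36.6% ± 12.3, and H3c2 and H2bc13 were covered in 1 library only.

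**Figure D4:**
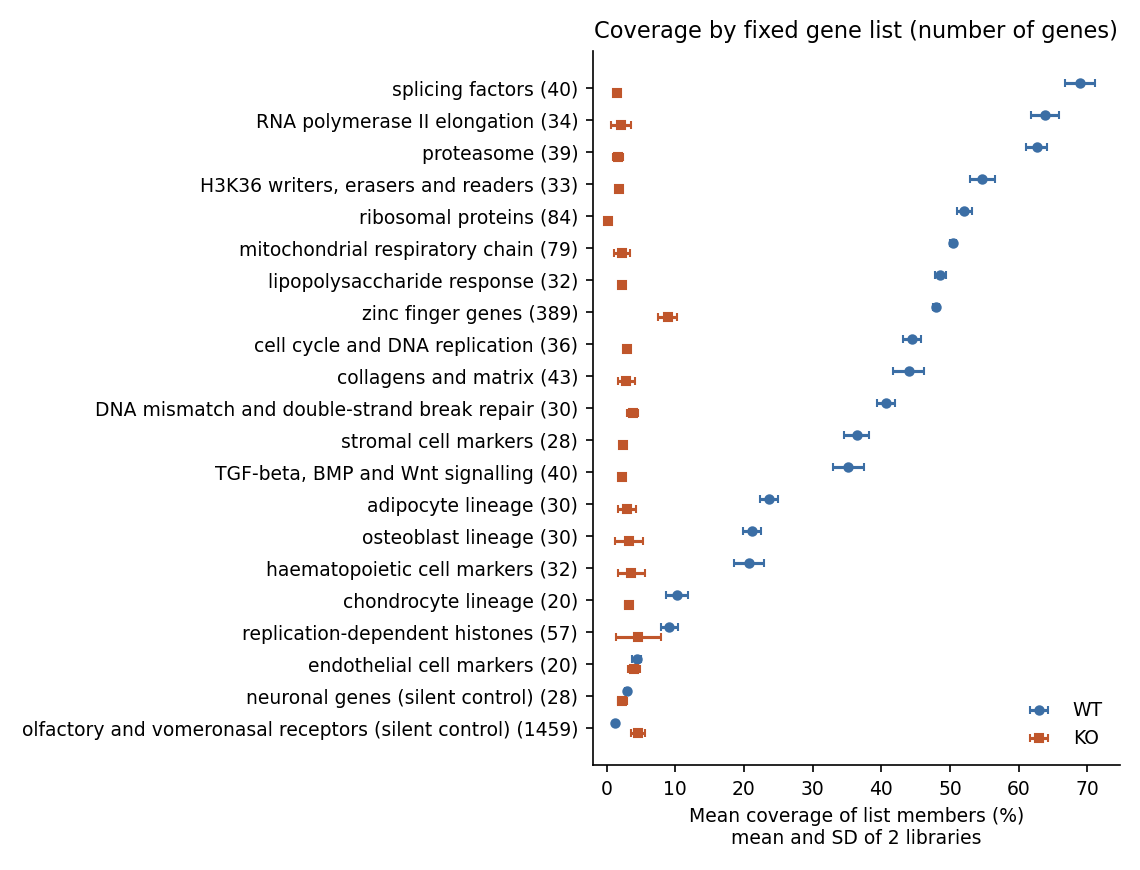
Mean coverage (%) of all found members of each fixed gene list in WT (blue) and KO (red), as mean and SD of 2 libraries, with the number of genes in parentheses. Splicing factors are highest in WT at 68.9%, and zinc finger genes are highest in KO at 8.89%, although their median change turns from -45.8 to 2.10 points once libraries are scaled to their mean coverage.

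The counts adjusted over the list alone were the same in 19 of the 21 lists. This says little, because adjustment hardly changes calls where most tested genes fall. Adjusted over the list alone, 38 collagen and matrix genes fell, and 1 olfactory or vomeronasal gene fell and 11 rose. In fry, which tests whether the genes of a list move on balance 1 way, 17 of 18 lists fell, with adjusted p of at most 0.0115, all but the olfactory list. Since 92.6% of all tested genes were lower, most lists drawn from them would fall in fry. It therefore does not set a list apart from other genes. Camera, which compares a list with all other tested genes, called 4 lists of 18 with its preset correlation. Splicing factors (adjusted p = 0.0226) and RNA polymerase II elongation (adjusted p = 0.0462) lost more percentage points than other genes. Their adjusted p = 0.701 and 0.726 with an estimated correlation. Both lists had much WT coverage to lose, with means of 68.9% and 63.8%. They were not compared with genes of equal WT coverage, so a greater loss in proportion is not shown. Splicing factors lost the call against IgG, against both controls, without KO replicate 1 and at a filter of 25%. RNA polymerase II elongation lost it in these settings too, whichever library was left out, with the replicate block, on the arcsine scale and with the higher scores. The zinc finger list was not called (adjusted p = 0.956), but it was called above other genes in 5 settings, after scaling (adjusted p = 4.21e-13), without WT replicate 1 or 2 (adjusted p = 0.0076 and 0.0071), at a filter of 25% (adjusted p = 0.0364) and in genes of at least 5 kb (adjusted p = 0.0465), and below them in 1, without a filter (adjusted p = 8.85e-05). The other 2 called lists were the olfactory and histone lists, which are not read as less loss than in other genes: tested receptors mostly entered through KO peaks, and the histone call (adjusted p = 1.3e-12) had an adjusted p = 0.559 with an estimated correlation, while the median change and fry pointed down. The osteoblast, adipocyte and haematopoietic lists were above other genes in camera with negative medians and no call, though the haematopoietic list was called after scaling (adjusted p = 0.0185).

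Several falls were in proportion smaller than the fall in mean coverage. KO coverage was 2.09% and 2.59% of bases in genes of 0% in WT, and only 3.78% and 4.62% in genes above 75%. Genes of low WT coverage therefore tend to turn higher after scaling, and the sign is no measure of mark kept by a single gene. After scaling to mean coverage, the values of Runx2, Lpl, Lcp1, Egfl7, Dnmt3b, Brca1, Msh3, Orc1, Sfrp1, Ticam2 and Olfr99 were higher in KO than in WT, as were those of Fabp4, Klf15, Cd79b, Timp1, Porcn, Il1b and Psmb11, which had not passed. Of the 107 genes named by the fixed rule, 101 were tested, 76 fell, 12 rose and 13 did not pass. Leaving out any 1 library ended the calls of part of them, and others then lay below the coverage filter and were not tested. Against IgG, 65 of the 101 kept at least 2/3 of their change, 24 had a smaller change or one of the other sign and 12 had no peak in any library. The 24 included Hmgxb3, Sparc, Fasn, Col11a2, Lyz2, Ccne1, Cdc6, Thbs2, Bmp1, Olfr99, Zfp384, Mroh2a and 8 of the 9 named rises of at least 10 kb. The 12 were Col1a1, Vim, Tubb3, Timp1, Atp5b, Olfr1417, Olfr1377, Olfr1339, H3c4, H3c2, H2ac1 and H2bc13.

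Gene length and position within genes were compared last. Across 5 groups of tested genes by length, the median change was -41.1 points in the shortest (up to 7.26 kb), -55.1, -54.4 and -51.6 in the middle groups, and -36.5 in the longest (from 56.2 kb). WT coverage was also lowest in the longest genes, with medians of 40.2% and 38.7%. Because the gene table used gives no strand, positions were folded from either gene edge to the middle. Coverage rose toward the middle in both genotypes. The inner bins were covered 1.217 times as much as the outer bins in WT and 1.212 times in KO, over 10324 genes (exact permutation p = 1). The end of a gene with more coverage was the same in both WT libraries in 93.7% of 5532 genes, in WT and KO libraries in 66.5% to 67.6%, and in both KO libraries in 65.3% of 2831 genes. The exact 95% interval of the last share is 63.6% to 67.1% and covers counting error only.

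**Figure D5:**
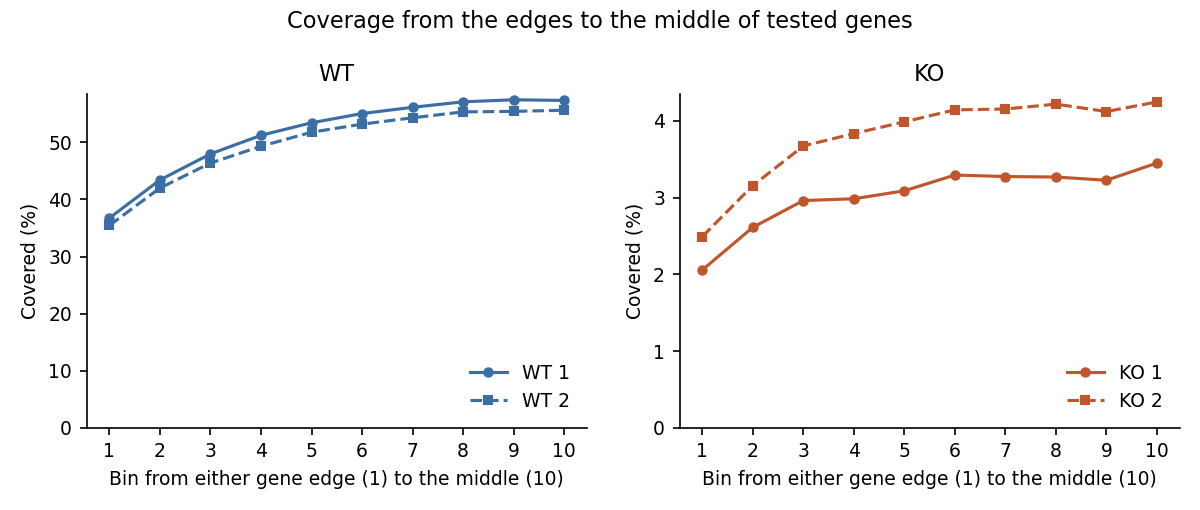
Percent of tested gene spans covered by peaks in 10 bins from either gene edge (bin 1) to the middle (bin 10), in WT (left) and KO (right, with its own scale), 1 line per library. Coverage rises in all 4 libraries between bin 1 and bin 10, from 36.7% and 35.5% to 57.3% and 55.6% in WT, and from 2.06% and 2.49% to 3.45% and 4.25% in KO.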

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

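Settings for the X chromosome, the length groups and the count of named genes that fell, and the restriction to genes of at least 5 kb, were chosen after the data had been seen; the others were planned. The fall in covered genome and the fall in the share of covered bases within protein-coding genes kept their direction in every setting run. Genes with lower coverage outnumbered those with higher coverage in every setting, but after scaling they were 45.2% of the tested genes, no longer most of them. Read depth is unknown and limits all of them, since a shallow library loses peaks first in weakly covered genes. Where a result below did not hold, the cause was not tested, except that fewer genes were tested under a stricter filter or in longer genes and fewer samples without a library. Exon-only and downstream-part coverage were not run.

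The ratio of KO to WT peak numbers (0.577) was 0.455 against IgG, 0.468 for bases covered against both controls and 1.11, reversed, with peaks within 1 kb merged; without 1 library it ran from 0.501 to 0.652. The ratio of covered genome (0.347) was 0.272 against IgG, 0.275 against both controls and 0.439 with an equal number of top peaks, and 0.30 to 0.395 without 1 library. WT regions without a KO peak (82.2%) were 87.3% against IgG, 87.5% against both, 87.9% with the higher scores, 65.6% merged and 90.4% where 50% of a region had to be covered, and 78.4% to 90.8% without 1 library. KO regions without a WT peak (59.4%) were 65.4%, 66.9%, 69.5%, 58.9% and 64.0% in the same settings, 60.1% where 10% had to be covered, and 68.8% to 72.1% without 1 library. The overlap of WT and KO lists (4.43%) was 3.16% against IgG, 3.05% against both and 2.57% with the higher scores, and 4.09% to 4.77% without 1 library. The difference in the share of protein-coding spans (-46.0 points) was -46.3 against both and -52.5 with the higher scores, and -46.2 to -45.8 without 1 library. The difference between KO and WT in the ratio of inner to outer bins (-0.00524) was -0.0414 against IgG, -0.0315 against both, -0.0320 with the higher scores and 0.0284 in genes of at least 20 kb, and -0.0278 to 0.00113 without 1 library.

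Genes with lower coverage (10013) were 4890 after scaling to mean coverage and 5883 at a filter of 25%, and 7867 to 9602 without 1 library. Genes with higher coverage (60) were 21 against IgG, 18 against both, 21 with the higher scores, 261 after scaling, 492 without a filter, 18 at 25% and 17 among genes of at least 5 kb, and 26 to 200 without 1 library. Called lists (4) were 1 against IgG, 1 against both, 10 after scaling, 18 without a filter, 2 at 25% and 1 with an estimated correlation, and 1 to 6 without 1 library. The X chromosome ratio (0.940) was 0.728 against IgG and 1.32, reversed, with the higher scores, and 0.800 to 1.08 without 1 library. The gap between the longest and the second group of lengths (18.6 points) was 14.5 against IgG and 14.6 against both, and 16.6 to 19.8 without 1 library. Named genes that fell (76) were 43 after scaling and 55 to 66 without 1 library.

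Counts of genes that fell per list moved in 54 comparisons with the main setting, most often after scaling. After scaling they were 7 in the osteoblast list (13), 5 adipocyte (13), 1 chondrocyte (3), 11 stromal (18), 3 haematopoietic (16), 0 endothelial (1), 0 neuronal (1), 9 DNA repair (27), 11 cell cycle (27), 17 collagen and matrix (37), 16 TGF-beta, BMP and Wnt (28), 40 respiratory chain (71), 2 olfactory (5) and 59 zinc finger (327). Without WT replicate 1 and 2 they were 8 and 8 haematopoietic, 0 and 0 endothelial, 20 and 17 olfactory and 202 and 213 zinc finger, and without KO replicate 2 they were 3 olfactory. Against IgG, and against both controls, they were 6 osteoblast, 0 endothelial, 0 neuronal, 2 olfactory and 1 histone (3). With the higher scores they were 5 haematopoietic, 0 endothelial and 1 olfactory, and with merged peaks 2 endothelial. At a filter of 25% they were 7 osteoblast, 6 adipocyte, 2 haematopoietic, 0 endothelial, 0 neuronal, 11 DNA repair, 19 collagen and matrix, 12 TGF-beta, BMP and Wnt, 42 respiratory chain, 3 olfactory and 1 histone. Without a filter they were 5 chondrocyte, 2 endothelial and 3 neuronal, and among genes of at least 5 kb 13 ribosomal (68), 1 olfactory and 1 histone.

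Among the named genes 21 changed sign after scaling, to 6.36 points for Runx2, 9.75 for Fabp4, 14.97 for Lpl, 165 for Zfp992, 142 for Zfp991, 145 for Gm51425, 22.4 for Klf15, 51.5 for Cd79b, 7.96 for Lcp1, 3.47 for Egfl7, 3.27 for Dnmt3b, 5.00 for Brca1, 10.98 for Msh3, 4.49 for Orc1, 3.77 for Timp1, 9.19 for Sfrp1, 5.01 for Porcn, 67.0 for Il1b, 43.3 for Ticam2, 22.8 for Olfr99 and 41.9 for Psmb11. Scaling multiplies all genes of a library by the same factor. Such a change of sign means only that a gene fell by a smaller proportion than mean coverage, to which genes of low WT coverage are prone. Scaled values are no longer percents of a gene span. Against IgG, Zfp660 became -3.86, Zfp978 -1.84 and Cd79b 7.99. Against both, Zfp978 became -2.85 and Cd79b 7.99. With the higher scores Zfp978 became -6.33, and with merged peaks Il1b became 3.88. Without 1 library, Cd79b ran from -22.3 to 15.9, Il1b from -1.10 to 1.08 and Psmb11 from -33.9 to 1.61. Over the settings, among named genes still tested in each, 1146 values kept their sign and side of the threshold. Of the others, 133 lost the call, 11 gained one and 33 changed sign. Genes that fell below the filter of a setting are not counted, so more calls were lost than this.

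The replicate number as a block is a pairing that only the numbers give. Deviations of the same-numbered libraries had a correlation of -0.00333 across 10809 genes, which are not independent replicates. This gives no sign of a pairing. KO coverage is low in most tested genes, so a shared deviation could go unseen, and whether the samples are paired is unknown. With the block, 9993 genes were lower and 60 higher, and 3 lists were called in camera.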

Other observations

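The gene groups in the next 2 paragraphs, and the tests of an uneven Input, of residual mark at WT sites, of positions that any library tends to call, of abundantly transcribed genes and of lost genes by length, were chosen after values had been seen; the other tests were written before.

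Long non-coding RNA genes as a group did not fall. Mean coverage over 5403 such genes of at least 5 kb apart from protein-coding spans was 3.01% and 2.97% in WT and 3.33% and 4.51% in KO. Of these, 28 were covered over at least 50% of their span in both WT libraries and 0 in both KO libraries, and 21 of the 28 were under 10% in both KO libraries, a fall favoured by choosing genes of high WT coverage. Malat1, an abundant nuclear RNA, had 60.5% ± 5.98 in WT and 3.74% ± 5.30 in KO (SD, n = 2), and Tug1 had 74.4% ± 4.16 and 2.91% ± 4.11. Snhg17, a host gene of small nucleolar RNAs, had 81.2% ± 1.04 and 3.54% ± 5.01, Pvt1 had 52.3% ± 1.02 and 2.44% ± 1.25, and Carmn had 54.9% ± 0.931 and 1.73% ± 2.45. Neat1, which lies beside Malat1 on chromosome 19, had only 25.5% ± 3.67 in WT. H19 had 0% in all 4 libraries.

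The Hox clusters mark position along the body axis. In the Hoxa cluster 4 of 11 genes were covered over at least 20% in both WT libraries, Hoxa2 (61.3% ± 0.878), Hoxa3 (22.8% ± 0.559), Hoxa5 (22.7% ± 1.62) and Hoxa6 (54.7% ± 27.0), and no gene of the 10 Hoxb, 9 Hoxc or 9 Hoxd genes was. The cut of 20% narrowly left out Hoxc5 (21.2% ± 7.79) and Hoxc13 (20.6% ± 7.95), each above it in 1 WT library, so it does not set the clusters apart. In KO, Hoxa2 and Hoxa5 had 0% and Hoxa6 had 15.5% ± 0.667. On the X chromosome, 10 of 685 genes of at least 5 kb (1.46%) were covered over 50% in both WT libraries, beside 4525 of 16096 autosomal genes (28.1%). Mean coverage of these X genes was 10.3% in WT and 2.19% in KO, so the mark fell over X genes although the covered share of the whole chromosome differed little. Xist, the non-coding RNA of X inactivation, had 29.2% ± 6.02 in WT and 1.12% ± 1.59 in KO. None of these values was tested.

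Zinc finger genes had higher KO coverage than other genes with the same WT coverage, WT score and length, with medians of 5.77% and 8.48% in the KO libraries beside 1.41% and 2.25% in matched genes. Cells that escaped Cre would leave the same residue in matched genes, but the zinc finger median lay at percentile 100 of 10000 matched lists in both KO libraries. An uneven Input library is argued against in the same way, since the percentile was also 100 in both KO lists called against IgG. Reads shared between near-identical copies in clusters stay open: the 80 zinc finger genes with no other within 1 Mb had 3.58% and 3.21%, beside 1.76% and 2.29% in matched genes, and the lower percentile was 95.29. Against IgG the lower percentile of the isolated genes was 94.15. Escaped cells and an uneven Input are therefore argued against only for the list as a whole, of which 259 of 339 tested genes are clustered. Mark that is placed at zinc finger genes without Setd2 may also contribute and was not tested.

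The KO peaks lay all over the genome, yet more often on WT regions than moved peaks did, by 1.90 and 1.78 times. The Input shared by both KO libraries is argued against as the source of their agreement, since the overlap of KO lists made against different controls was still 2.93 and 2.96 times that of moved peaks. Residual H3K36me3 at WT sites predicts the ratio of 1.78, but so does a tendency of any library to call the same positions. After moves of 5 to 30 kb the ratio was 2.52 and 2.29 at WT regions outside annotated genes. It was 1.44 and 1.39 in genes with at least 50% WT coverage. This comparison cannot decide between the explanations. Where WT regions are dense, moved peaks land on them again more often, which lowers the ratio whatever the cause. KO coverage was lowest in genes of 0% in WT, with 2.09% and 2.59% of their bases covered. Genes above 0% to 10% in WT had 2.57% and 3.45%, and those above 10% to 25% had 3.11% and 4.03%. Those above 25% to 50% had 2.81% and 3.68%, and those above 50% to 75% had 2.89% and 3.67%. The rise of KO coverage with WT coverage was therefore not steady. It was highest above 75%, with 3.78% and 4.62%. Among genes of at least 20 kb, the end with more coverage was the same in both KO libraries in 65.5% of those with at least 25% WT coverage. Under 10% WT coverage this share was 56.8%. For the WT libraries these shares were 94.2% and 71.4%. Residual mark cannot be told apart from that tendency, because both raise the overlap and the lists hold no read counts.

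Of 8099 genes covered over at least 30% in both WT libraries against Input, 126 were covered under 5% against IgG, among them Fn1 (76.2% and 0%), Thbs1 (79.7% and 0%), Eef2 (86.9% and 0%) and Hsp90ab1 (73.4% and 0%). Of genes matched on length, coverage and score, 9.37% were lost, with a bootstrap 95% interval of 7.70% to 10.99% around the bound of 10% set for this test. Short genes or weak signal are argued against in the 15 lost genes of at least 10 kb, Fn1 and Thbs1 among them, since 1.33% (0.333% to 2.33%) of genes matched to these were lost. In the 111 shorter genes they stay open, with 10.45% (8.65% to 12.16%). Reads at abundantly transcribed genes in the WT IgG library stay open too. Lost genes were more frequent among ribosomal proteins (8 of 59, Fisher's exact p = 3.13e-06) and collagens and matrix (6 of 30, Fisher's exact p = 5.5e-06), with adjusted p of 2.82e-05 and 3.3e-05 over 18 lists, while 0 of 283 zinc finger genes were lost. Lost genes were also more frequent in 3 other lists by Fisher's exact test. These were stromal markers (3 of 16, adjusted p = 0.00799), osteoblast genes (2 of 10, adjusted p = 0.0299) and histone genes (4 of 5, adjusted p = 4.97e-06). Other rows go against reads at abundantly transcribed genes. In the silent olfactory list 2 of 6 receptor genes were lost (Fisher's exact adjusted p = 0.0124), but 0 of 39 splicing factor and 0 of 36 proteasome genes. The lists hold no measure of transcription, so in genes under 10 kb this cannot be told apart from short genes or weak signal. No biological explanation was tested, and the single WT IgG library could itself stand apart.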
